A study of Mus musculus with 4 samples.

How the data were processed

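Each of the 4 samples, 2 of mTEClo and 2 of mTEChi sorted from mouse thymus, had 1 peak list made with CUT&RUN on 500000 cells. Groups and replicate numbers were taken from the sample titles. The labels do not say whether replicates came from separate mice, so p-values over libraries measure only the spread between these libraries, which may be technical. The titles name an antibody against p53 and the protocol text one against BAF155; neither was preferred in the analysis, and "anti-p53" is used as a name only.

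Per the submitters' processing notes, Bowtie2 2.2.9, Picard, SAMtools 1.9 and MACS2 2.2.7.1 were used with the mm10 genome; their settings and any control for peak calling are not given in the sources used here. The deposited files list intervals of 1 fixed width, a summit with 150 bp on each side, for every library separately, so replicates were not pooled by the authors. The score deposited with each peak was read as the −log10 of a p-value or q-value given by the authors' peak caller; which of the 2 it is was not stated, and its minimum of 2.00 in each list corresponds to a limit of 0.01. It served only to rank or filter peaks within a list. Scores are coarse: the 4 most frequent values of a list covered 38.7% to 51.1% of its peaks, so ranks hold many ties. No list held intervals that overlap each other, and between 1531 and 3759 peaks per list carried a name that marks them as part of a split peak. Read counts and sequencing depth are not in peak lists, so depth is unknown. Wilson intervals for shares of peaks cover counting error only.

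Coordinates are mm10, written from 1. Genes came from a RefSeq table of the same assembly (GRCm38.p6) with start and end but without strand or exons, and 21631 protein-coding genes were used. Distances planned to a transcription start were therefore measured from the summit to either end of the gene interval, and exon, intron and promoter classes were not assigned. A mm10 sequence was not used here, so the planned search for the p53 motif and 9 other motifs, and the comparison of motifs in state-specific regions, were not run. Of 324 distinct genes in the 14 gene lists, 323 matched a symbol or synonym; Trp53cor1 did not, and the older name Expi was read as Wfdc18.

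Peaks counted as overlapping when they shared at least 1 bp. Chance overlap and chance distance came from 100 circular shifts of a list along its chromosomes (20 by quartile of score). Peaks of the 4 libraries were merged into regions, and a region was specific to a state when both of its libraries and neither of the other state held a peak; the same count was made for all 3 divisions of the libraries into pairs. A gene was called in a library when a summit lay within 5 kb of either end. Lists were compared with all other protein-coding genes by the two-sided Fisher exact test, with Benjamini-Hochberg adjustment over 14 lists within each state and a threshold of 0.05. Between states, members called in both libraries of 1 state alone were compared by an exact sign test. Values per library were compared by the two-sided exact permutation test. Genes and regions are not replicates, so tests over them describe these libraries.

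The lists, tests, alternatives and the rule for named genes were fixed before the data were examined. The rule named up to 10 p53 targets called in all 4 libraries and up to 4 of each state-specific class, up to 4 and 3 for each other list, the 10 regions shared by all 4 libraries and the 8 specific to each state with the lowest worst rank, named by the nearest protein-coding gene within 50 kb, and always Trp53, Mdm2, Cdkn1a and Aire. A gene that the rule names among the sensory tissue genes is not reported here. Alternatives were the peaks above each list's median score, equal list lengths of 69359 peaks, the 10000 highest peaks, each library left out in turn, summits within 75 bp in place of overlap, gene end distances of 250 bp and 3 kb, gene windows of 1 and 25 kb, the gene body with 5 kb, and the replicate number as a block. Settings that cut a list by score kept a fixed number of peaks, and the cut at the median kept each list down to its middle peak. Peaks tied at a cut were kept or dropped by 1 random draw with a fixed seed.

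The region and list steps were tested on simulated data over 287369 regions and 21631 genes. Of planted regions, 5101 in all 4 libraries gave 5106, while 3000 mTEClo-only and 2000 mTEChi-only regions gave 3937 and 3052, since single-library peaks also overlap by chance. Of at least 101 planted list members called in both mTEClo libraries, 121 were counted. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.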

Results

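Sites cut by an antibody-targeted nuclease were compared between 2 populations of mouse medullary thymic epithelial cells, mTEClo and mTEChi, with 2 libraries of each. The assay, CUT&RUN, recovers short DNA fragments released by a protein A-MNase fusion around an antibody bound to chromatin in permeabilised cells. Medullary thymic epithelial cells show self-antigens to developing T cells. In common usage the lo cells carry little surface MHC class II and are less mature, while the hi cells carry much of it and include the cells that express Aire, a regulator of tissue-restricted antigen genes. All cells were wild type for Trp53, the gene of the transcription factor p53, and 500000 cells were used per condition. The sample titles name an antibody against p53, whereas the protocol text of the same samples names one against BAF155, a subunit of the BAF chromatin remodelling complex. The peaks are described here under the titles' name, anti-p53, and the labels do not settle which protein they mark. The series title ties p53 repression to chromatin accessibility in thymic epithelium, and the comparison asks where the signal lay in each cell state.

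The deposited lists held 89809 and 69359 peaks in mTEClo replicates 1 and 2 and 73510 and 85308 peaks in mTEChi replicates 1 and 2. They covered 27, 20.9, 22.1 and 25.7 Mb of the mm10 genome, in intervals that reach 150 bp to each side of a summit. The mean was 79584 ± 14460 peaks (SD, n = 2) in mTEClo and 79409 ± 8342 (SD, n = 2) in mTEChi, and the difference of 175 peaks was far below the spread between replicates (two-sided exact permutation test, p = 1). With 2 libraries against 2 the smallest p such a test can give is 0.333, so no value per library could pass a threshold of 0.05. Sequencing depth is unknown, and no library made with a control antibody was analysed here, so the lists carry no background measured in the same way.

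Most of the strongest sites were found in both cell states: of the 500 highest scores of each list, 98.6% and 93.8% in mTEClo replicates 1 and 2 and 97.6% and 98% in mTEChi replicates 1 and 2 overlapped a peak of at least 1 library of the other state. The highest score of every list lay at a single position, chromosome 8 from 118847013 to 118847314, inside the gene interval of Cdh13, which encodes a cadherin, and 477765 bp from the nearest end of a protein-coding gene. Its authors' scores were 108 and 134 in the mTEClo libraries and 276 and 156 in the mTEChi libraries. The next regions by their worst rank over the 4 libraries lay close to a gene end at Sp1, the gene of a transcription factor (chromosome 15, 102405709 to 102406186, 296 bp from the gene end), and at Cdca2 (chromosome 14, 67715685 to 67716019, 13 bp). After these came a region 6602 bp from Wdr81 (chromosome 11, 75461255 to 75461565). Uvrag (chromosome 7, 99141195 to 99141508), Rnf5 (chromosome 17, 34603694 to 34604040), Snrnp70 (chromosome 7, 45395691 to 45396012), Khsrp (chromosome 17, 57031618 to 57031992) and Zbtb20 (chromosome 16, 42875431 to 42875791) followed, each between 79 and 327 bp from a gene end. The list of 10 was completed by a region inside the interval of Hnrnpl (chromosome 7, 28810572 to 28810903), 2190 bp from its end.

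Merging the 4 lists gave 259773 regions, of which 5162 (1.99%) held a peak in all 4 libraries, 7739 (2.98%) in 3, 25129 (9.67%) in 2 and 221743 (85.4%) in 1. Regions in all 4 libraries lay within 1 kb of an end of a protein-coding gene in 50.6% of cases (95% Wilson interval 49.2 to 52.0). That share was 27.4% (26.4 to 28.4) for regions in 3 libraries, 13.3% (12.8 to 13.7) in 2 and 5.48% (5.38 to 5.57) in 1. Sharing followed the authors' score within each list. In the highest quartile by score, 54.7% and 51.2% of mTEClo peaks and 61.3% and 42.7% of mTEChi peaks (replicates 1 and 2) overlapped a peak of another library, against 20.5%, 22.6%, 18.5% and 18.4% in the lowest quartile. Peaks shifted along their chromosomes overlapped another library in 4.93% to 5.45% of cases.

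**Figure D1:**
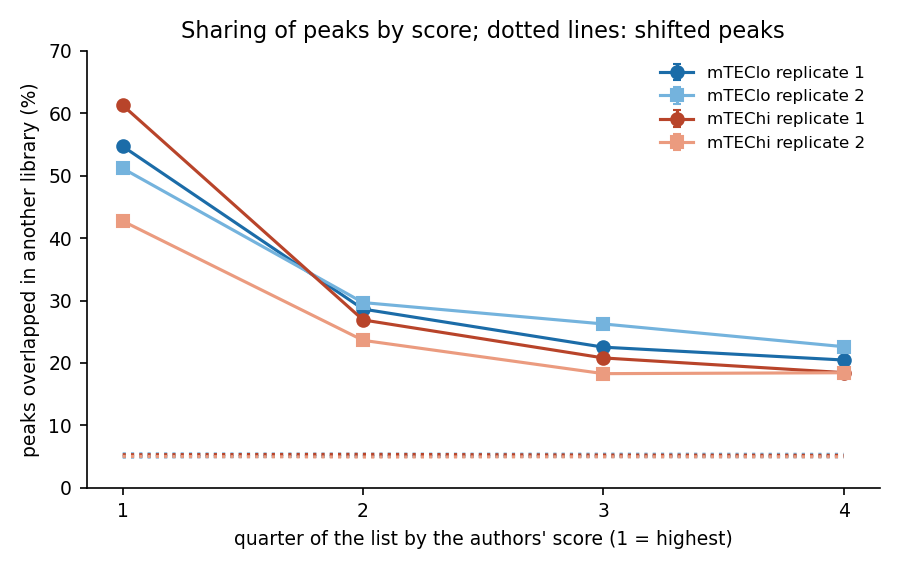
Percent of peaks (vertical axis) that overlapped a peak of at least 1 other library, by quartile of the authors' score within each list (horizontal axis, 1 is the highest), with 1 line per library; the 95% Wilson intervals are smaller than the markers, and dotted lines give shifted peaks. All 4 lines fall from between 42.7% and 61.3% in the highest quartile to between 18.4% and 22.6% in the lowest, above the dotted lines near 5%.

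Libraries of 1 state resembled each other slightly more on average than libraries of different states, with overlapping ranges. Of the peaks of mTEClo replicate 1, 18.5% overlapped a peak of mTEClo replicate 2, and 18.4% of the peaks of mTEChi replicate 1 overlapped one of mTEChi replicate 2. Between states the share ran from 14.4% to 16.7% over the 4 pairs, each counted from the mTEClo library. Counted from the other library of each pair there was no such gap: the share was 23.8% and 15.8% within mTEClo and mTEChi and 11.7% to 20.3% between states. Shifted peaks gave 1.73% to 2.11%, so the observed overlap, counted from the first library, was 6.80 to 10.7 times that of shifted peaks. Shifting also removes the concentration of peaks at gene ends. Lists that share only that concentration could therefore overlap more than shifted peaks. The Jaccard index over base pairs averaged 0.0705 within states and 0.0555 between states, a ratio of 1.27. The 2 kinds of pair were not separated, since the mTEChi pair (0.0626) lay below the pair of both first replicates (0.0677), and the ratio was 1.03 without mTEClo replicate 2 and 1.58 without mTEChi replicate 1.

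State-specific regions, those with a peak in both libraries of 1 state and in neither of the other, numbered 7144 for mTEClo and 4766 for mTEChi; with the 10000 highest peaks of each list the order turned, to 1008 and 1122. The leading mTEClo-only region lay inside Slc25a54, a gene of the mitochondrial carrier family (chromosome 3, 109082454 to 109082787, scores 18.9 and 13.8). Others lay inside the intervals of Hunk, Efcab14 and Plxdc1 and within 50 kb of Ksr1, Cdc42 and Insig2, and 1 (chromosome 2 from 94737570) had no protein-coding gene end within 50 kb. The leading mTEChi-only region, on chromosome 9 from 11380627 to 11380951 (scores 28.8 and 26.5), lay 476014 bp from the nearest gene end, and regions on chromosome 8 from 44456282 and chromosome 1 from 13501998 had none within 50 kb either. The remaining leading mTEChi-only regions lay 12291 bp from Tmigd1 (chromosome 11 from 76928719, scores 28.5 and 24.6) and inside Serpina3j, Adap1, Elavl2 and Eif2ak3, the last encoding an endoplasmic reticulum stress kinase. None of the leading regions of either state lay within 1 kb of a gene end.

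The split by state gave more pair-specific regions than the other 2 ways of dividing the 4 libraries into pairs: 11910 in total, against 6940 for replicate 1 against replicate 2 (ratio 1.72) and 6279 for the crossed division (ratio 1.9). Near gene ends lay 12.8% of mTEClo-only and 10.3% of mTEChi-only regions, an odds ratio of 1.28 (95% interval 1.14 to 1.44, Fisher's exact test, p = 2.68e-05). Regions are not replicates, so this describes these libraries. The division by replicate gave a wider gap, 17.3% for the first and 10.6% for the second replicates. The crossed division gave 14.3% with mTEClo replicate 1 and 13.7% with mTEClo replicate 2. The gap between the states therefore cannot be told apart from differences between libraries. Without a library of a state, 1 list suffices for the call, and the counts rose to 54407 and 68954 for mTEClo (without replicates 1 and 2) and to 68349 and 55162 for mTEChi. Leaving out mTEClo replicate 1 raised the mTEChi-only count to 7375.

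**Figure D2:**
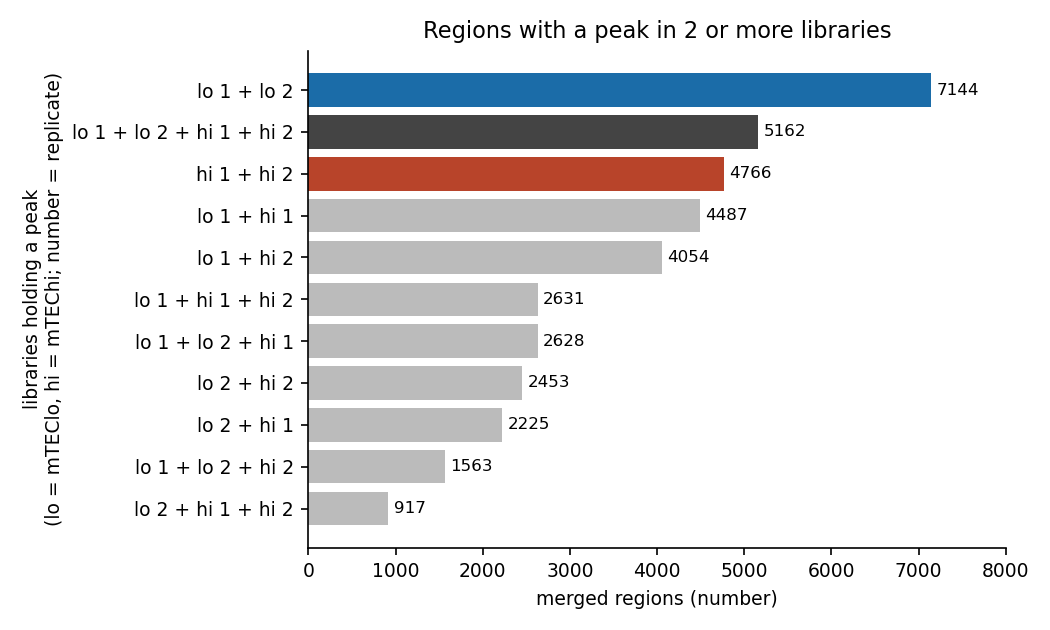
Number of merged regions (horizontal axis) for each combination of 2 or more libraries that held a peak (vertical axis; lo is mTEClo, hi is mTEChi, numbers are replicates). The pair of mTEClo libraries alone held 7144 regions, all 4 libraries 5162 and the pair of mTEChi libraries alone 4766, while the 4 pairs across states held 2225 to 4487.

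Peaks were concentrated at the ends of protein-coding genes in both states. Within 1 kb of a gene end lay 12.7% (95% Wilson interval 12.5 to 12.9) and 11.4% (11.2 to 11.7) of mTEClo peaks and 11.5% (11.3 to 11.8) and 9.95% (9.75 to 10.1) of mTEChi peaks. These shares were 4.00, 3.61, 3.69 and 3.15 times those of shifted peaks. The means were 12.1% ± 0.910 (SD, n = 2) in mTEClo and 10.7% ± 1.13 (SD, n = 2) in mTEChi (two-sided exact permutation test, p = 0.667). The difference of 1.33 percentage points turned to -2.44 when the 10000 highest-scoring peaks of each list were used.

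At the level of genes, 69.2% and 59.7% of 21631 protein-coding genes had a peak within 5 kb of either end in mTEClo replicates 1 and 2, and 59.8% and 64.1% in mTEChi replicates 1 and 2. Both mTEClo libraries called 11106 genes, both mTEChi libraries 10400 and all 4 libraries 7793, while 764 genes were called in both mTEClo libraries and neither mTEChi library and 482 the other way.

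Genes that p53 is known to activate carried peaks more often than other genes in both states, although the mTEClo call was lost in 2 of 9 settings. Of 44 measured members, 40 and 35 had a peak in the mTEClo libraries and 42 and 39 in the mTEChi libraries, and 29 had one in all 4. Both mTEClo libraries called 33 (odds ratio against other protein-coding genes 2.85, 95% interval 1.40 to 6.25; Fisher's exact test, adjusted p = 0.0192 over 14 lists), and both mTEChi libraries called 38 (6.86, 2.88 to 19.9; adjusted p = 2.25e-06). Called in all 4 were Cdkn1a, the cell cycle inhibitor p21, the apoptosis genes Bax, Bbc3, Pmaip1 and Fas, and Ccng1, Trp53inp1, Sesn1, Sesn2 and Aen. Mdm2, the gene of the ubiquitin ligase that degrades p53, was the 1 member called in both mTEChi libraries and neither mTEClo library, and Ercc5, a DNA repair nuclease gene, the 1 member of the opposite kind, too few to test a difference between the states.

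Single target genes showed where these peaks lay. At Cdkn1a (chromosome 17, 29090979 to 29100722) both mTEChi libraries had their best peak at 29093713, inside the gene, with scores of 8.61 and 8.39, and mTEClo replicate 2 had one at 29093677 (6.24). The best peak of mTEClo replicate 1 was 3.62 at 29097655. At Mdm2 (chromosome 10, 117688875 to 117710758) the mTEChi summits stood 62 and 116 bp outside the gene's upper coordinate, with scores of 5.18 and 4.34, and no mTEClo peak lay within 10 kb of the gene. Aen, an exonuclease gene (chromosome 7, 78895927 to 78911209), had summits between 78895864 and 78895878 in all 4 lists, with scores of 22.3, 12.4, 27.6 and 17.1 in mTEClo replicates 1 and 2 and mTEChi replicates 1 and 2. Bax had scores of 7.35, 6.57, 20.6 and 17.2 in the same order, Bbc3 13, 4.93, 26.5 and 23.5, and Fas 3.62, 4.49, 12.6 and 14.2. The best Bax summits lay 1759 to 1816 bp outside the gene's lower coordinate. The best Fas peak of mTEClo replicate 2 lay at 34293798, apart from those of the other libraries (34290516 to 34290616). Pmaip1 had 4.60, 4.42, 5.07 and 2.45 and Sesn2 9.94, 4.89, 9.76 and 5.18. The Pmaip1 summits lay apart, at 66464292 and 66457945 in mTEClo and at 66459688 and 66459464 in mTEChi. Scores rank peaks within a list and are not compared as levels. Ercc5 (chromosome 1, 44146948 to 44181260) had mTEClo summits at 44147908 and 44147959, inside the gene, and 1 mTEChi replicate 2 peak lay inside it farther from its ends. With the gene body in the window, 0 targets were mTEClo-only.

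The mTEClo call for p53 targets did not hold in Fisher's exact test without mTEClo replicate 1 (odds ratio 2.63, adjusted p = 0.114) or with only the peaks above each list's median score (2.35, adjusted p = 0.0599), and its adjusted p ran from 0.00183 to 0.114 over the 9 settings that can change it. Peaks tied at the median were drawn at random once, so the result of that setting may depend on the draw. The mTEChi call held in its 9 settings (exact test, adjusted p up to 0.0150). Settings that leave out a library of the other state cannot change a call and are not counted here or for the lists that follow. The classes of Mdm2 and Ercc5 grew when a library was left out: without mTEClo replicate 1, 8 targets were called in the mTEChi libraries and not in the remaining mTEClo library, and 2 without mTEClo replicate 2 or without mTEChi replicate 2. Targets called in the mTEClo libraries alone numbered 3 without mTEChi replicate 1 and 2 without mTEChi replicate 2.

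**Figure D3:**
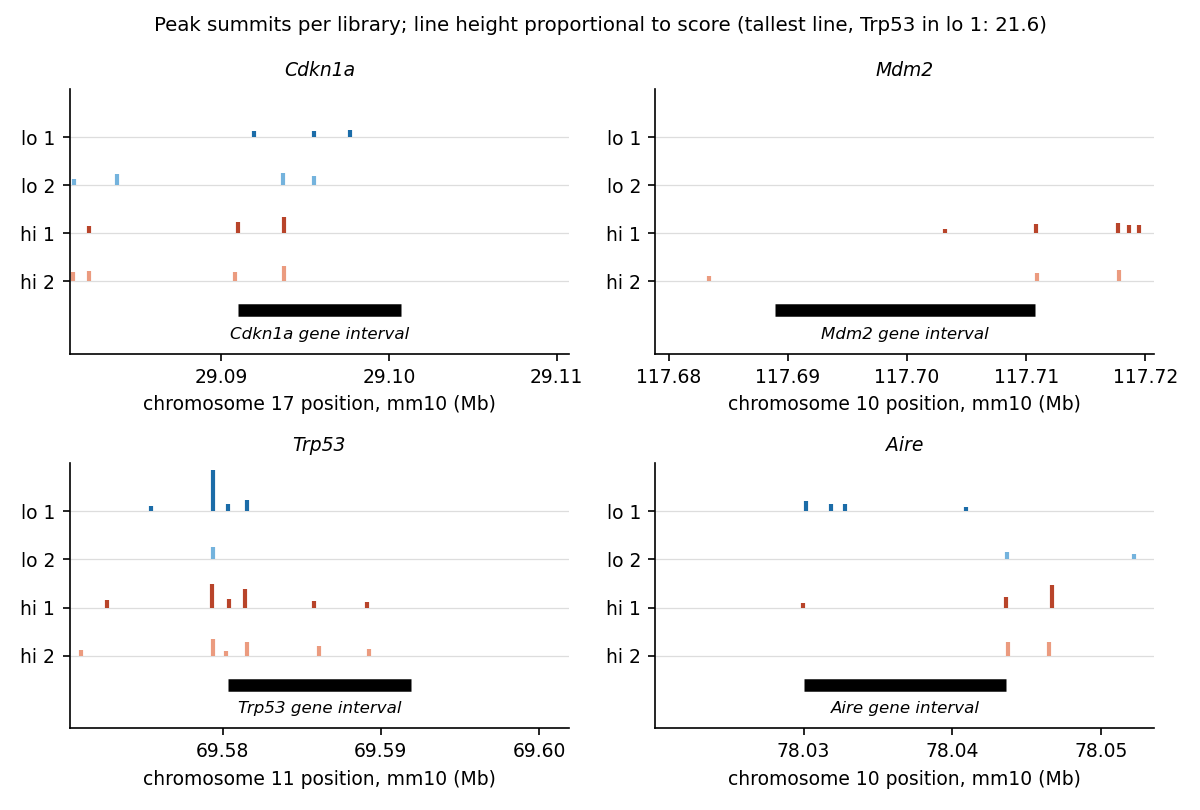
Peak summits at Cdkn1a, Mdm2, Trp53 and Aire, with 10 kb on both sides of each gene interval (black bar); the horizontal axis is the mm10 position in Mb, each grey line is 1 library (lo is mTEClo, hi is mTEChi) and line height is proportional to the authors' score, up to 21.6. At Mdm2 the mTEClo libraries have no summit, whereas at Trp53 all 4 libraries have one between 69579345 and 69579376.

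Genes of mature and general thymic epithelial identity were called often in the mTEChi libraries. Of 20 mature mTEC genes, which hold antigen presentation and Aire-related genes, both mTEChi libraries called 19 (odds ratio 20.6, 95% interval 3.27 to 854; Fisher's exact test, adjusted p = 8.25e-05) and both mTEClo libraries 15 (2.85, adjusted p = 0.126). Aire (chromosome 10, 78030022 to 78043610), Cd80, Cd40 and H2-Aa were among the 14 called in all 4, and Traf6 and Ctss, which encodes the antigen-processing protease cathepsin S, were called near their ends in both mTEChi libraries and neither mTEClo library, with 1 mTEClo replicate 1 peak inside Ctss. The best Aire peaks had scores of 5.66 and 3.94 in mTEClo and 11.8 and 7.22 in mTEChi. The mTEClo pair lay at opposite ends of the gene, at 78030179 in replicate 1 and 78043697 in replicate 2. The mTEChi pair lay 3126 and 2902 bp outside the gene's upper coordinate. Of 20 thymic epithelial identity genes, both mTEChi libraries called 18 (9.73, 2.33 to 86.5; exact test, adjusted p = 0.000677) and both mTEClo libraries 14 (2.21, adjusted p = 0.183). Foxn1, the master regulator of thymic epithelium, Epcam, Krt5 and Krt8 were called in all 4, and Trp63 in both mTEChi libraries and neither mTEClo library, with scores of 2.02 and 2.04 near its ends. Inside the whole Trp63 interval lay 13 and 12 mTEClo and 21 and 6 mTEChi peaks.

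Immature mTEC genes passed in neither state, with 14 of 20 called in both mTEClo libraries (odds ratio 2.21, adjusted p = 0.183, Fisher's exact test) and 12 in both mTEChi libraries (1.62, adjusted p = 0.473). Itgb4, Ackr4, Krt5 and Krt14 were called in all 4, and Itga6 near its ends in both mTEChi libraries alone, with 6 and 3 mTEClo peaks inside the gene. Between the states no list could be tested on its state-specific members: each list had at most 4, and the smallest p an exact sign test of 4 can give is 0.125. With a 25 kb window every member of the mature mTEC and identity lists was called in mTEChi, the odds ratio was infinite, and neither list passed (exact test, adjusted p = 0.103 for both). The identity list also missed the threshold with the 10000 highest peaks (1.80, exact test, adjusted p = 0.317). There the mature list passed in mTEClo as well (4.72, exact test, adjusted p = 0.0243). Over all settings the adjusted p (exact test) ran from 0.000135 to 0.103 for the mature and from 0.000273 to 0.317 for the identity list in mTEChi, and from 0.0243 to 0.314 for the mature list in mTEClo.

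Aire-dependent antigen genes were called less often than other genes in mTEChi, while the mTEClo list did not pass. Both mTEChi libraries called 6 of 25 (odds ratio 0.341, 95% interval 0.111 to 0.888; Fisher's exact test, adjusted p = 0.0382) and both mTEClo libraries 7 (0.368, adjusted p = 0.121). Crp, the gene of C-reactive protein, Pcp4 and Kcnj5 were called in all 4; Crp had scores of 17.3 and 13.8 in mTEClo and 5.07 and 4.34 in mTEChi. Fgg, a fibrinogen chain gene, and Wfdc18 were called in both mTEClo libraries alone and Fabp9 in both mTEChi libraries alone. The mTEChi call was lost in 4 of 9 settings (exact test, adjusted p 0.00188 to 0.782), among them without mTEChi replicate 2 (odds ratio 0.529, adjusted p = 0.212). The mTEClo list passed in 2 settings: with the gene body (0.329, exact test, adjusted p = 0.0462) and without receptor genes in the background (0.321, adjusted p = 0.0427; range 0.0427 to 0.831).

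Regulators of mimetic cells, medullary cells that adopt programs of other tissues, did not pass the test within 5 kb, with 15 of 26 called in both mTEClo libraries (odds ratio 1.29, adjusted p = 0.654, Fisher's exact test) and 11 in both mTEChi libraries (0.792, adjusted p = 0.749). Pou2f3 and Trpm5 of tuft cells, Spib and Sox8 were called in all 4, Ptf1a in both mTEClo libraries alone and Neurod1 in both mTEChi libraries alone. Within 1 kb the list passed as less often called in mTEChi, with 1 of 26 members (0.117, exact test, adjusted p = 0.0207; 0.0207 to 1 over the settings). Sensory tissue genes were called in 9 of 25 cases in mTEClo (0.533, exact test, adjusted p = 0.225) and 7 in mTEChi (0.420, adjusted p = 0.0731), where the list passed with equal list lengths (0.311, adjusted p = 0.0296; 0.0296 to 0.444 over the settings). Gnat1, Pde6a and Cryaa were among those called in all 4, the photoreceptor and pigment epithelium genes Cnga1, Gucy2e and Rpe65 in both mTEClo libraries alone and Otoa in both mTEChi libraries alone, all by gene ends. Inside the gene lay 5 and 3 mTEClo peaks for Otoa, 2 mTEChi replicate 2 peaks for Gucy2e and 1 mTEChi replicate 1 peak for Cnga1.

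Markers of other cells that a thymus sort could hold passed the test within 5 kb in neither state. Both mTEClo libraries called 9 of 20 thymocyte genes (odds ratio 0.775, adjusted p = 0.708, Fisher's exact test), 7 of 20 fibroblast and endothelial genes (0.510, adjusted p = 0.229) and 6 of 20 myeloid and B cell genes (0.406, adjusted p = 0.169). In both mTEChi libraries these counts were 9 (0.883, exact test, adjusted p = 0.826), 5 (0.360, adjusted p = 0.0731) and 8 (0.720, adjusted p = 0.595). Rag2, Ptcra, Cd3g, Cd5, Esam, Eng, Cd68, Spi1, Cx3cr1 and Cd79a were called in all 4 libraries. Cd3d, Cd8a and Pax5 were called in both mTEClo libraries alone, and Themis, Plvap and Cd79b in both mTEChi libraries alone. These classes refer to gene ends: inside Pax5 lay 11 and 2 mTEClo and 13 and 8 mTEChi peaks, and inside Themis 4 and 2 mTEClo peaks. Less often called in other settings were thymocyte genes within 1 kb in mTEClo (0 of 20, exact test, adjusted p = 0.0179; 0.0179 to 0.686 over the settings) and fibroblast and endothelial genes in mTEChi without receptor genes in the background (0.315, adjusted p = 0.0471; 0.0471 to 1).

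BAF subunit genes, whose products include the protein named in the protocol text, were called in both libraries of either state for 17 of 20 members (odds ratio 5.38 in mTEClo and 6.13 in mTEChi; Fisher's exact test, adjusted p = 0.0192 and 0.00384), calls lost in 8 and 5 of 9 settings. Smarca4, Smarca2, Smarcc1 (which encodes BAF155) and Smarcc2 were called in all 4, and Smarce1 in both mTEChi libraries alone. Housekeeping genes such as Gapdh, Tbp, Ppia and Rplp0 were called for 14 of 20 members in mTEClo (2.21, exact test, adjusted p = 0.183) and 16 in mTEChi (4.32, adjusted p = 0.0162, lost in 3 of 9 settings). Regulators of p53 were called for 11 of 20 in mTEClo (1.16, exact test, adjusted p = 0.825) and 15 in mTEChi (3.24, adjusted p = 0.0458, lost in 7 of 9 settings). Trp53 itself (chromosome 11, 69580348 to 69591873), Atm, Atr and Chek2 were called in all 4, with best scores at Trp53 of 21.6 and 6.81 in mTEClo and 12.4 and 8.58 in mTEChi. Mdm2, Cdkn2a and Trp63 were called in both mTEChi libraries and neither mTEClo library, with no member of the opposite kind; 0.25 is the smallest p an exact sign test of 3 members can give, and Trp63 held mTEClo peaks farther inside the gene.

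Cell cycle genes repressed through the DREAM complex were called for 21 of 30 members in both mTEClo libraries (odds ratio 2.21, adjusted p = 0.126, Fisher's exact test) and 17 in both mTEChi libraries (1.41, adjusted p = 0.473). Ccnb1, Ccna2, Cdc25c and Aurka were called in all 4, Ccna2 with scores of 19.7, 16.9, 22.5 and 11.3, and E2f2 was called in both mTEClo libraries alone (with 4 and 2 mTEChi peaks inside the gene) and Mcm6 in both mTEChi libraries alone (with 1 mTEClo replicate 2 peak inside). Within 1 kb the DREAM list passed in mTEClo, with 16 of 30 members (3.06, exact test, adjusted p = 0.0179; 0.0179 to 0.410 over the settings).

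The calls of the small BAF, housekeeping and p53 regulator lists moved across the threshold between settings. The BAF call was lost in 8 of 9 settings in mTEClo, among them without replicate 1 (odds ratio 3.83, exact test, adjusted p = 0.153) and replicate 2 (4.00, 0.119), and in 5 in mTEChi, among them without replicate 2 (3.82, 0.0512). The adjusted p (exact test) ran from 0.0427 to 0.514 and from 0.00737 to 0.707. The p53 regulator call was lost in 7 and the housekeeping call in 3 settings, both among others without mTEChi replicate 1. The odds ratio there was 3.17 for each (exact test, adjusted p = 0.107; ranges 0.00333 to 0.437 and 0.000109 to 0.782). The housekeeping list passed in mTEClo with the 10000 highest peaks (3.81, exact test, adjusted p = 0.0415; 0.0415 to 0.482).

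**Figure D4:**
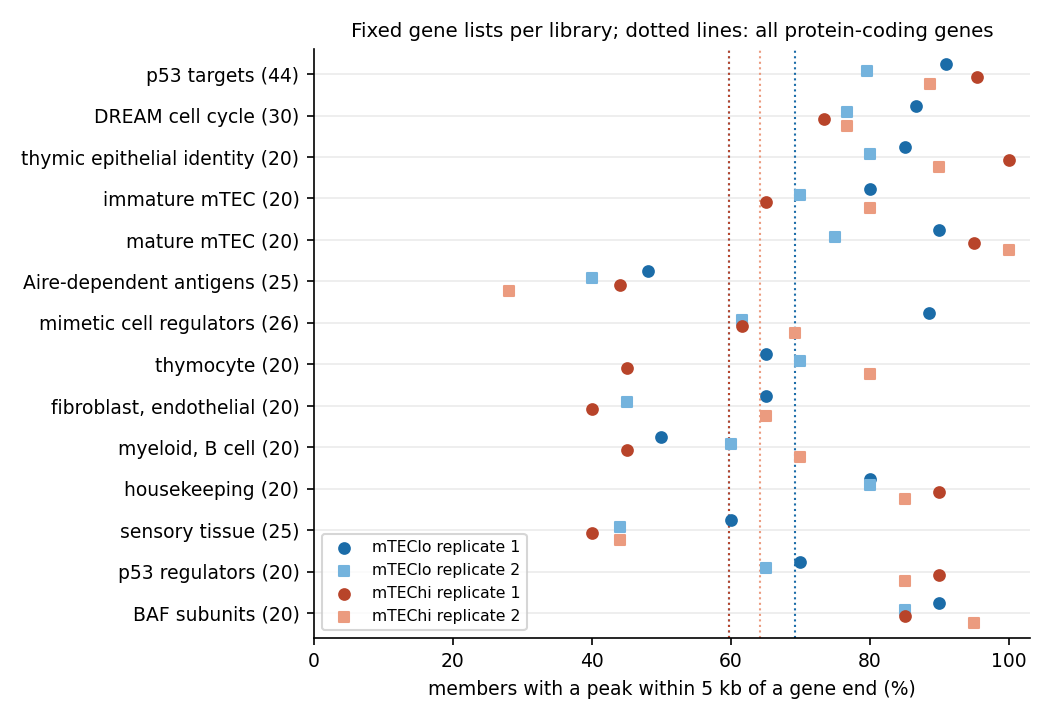
Percent of the measured members of each gene list (vertical axis, number of members in parentheses) with a peak within 5 kb of a gene end (horizontal axis), with 1 marker per library; dotted lines give all protein-coding genes, and those of mTEClo replicate 2 (59.7%) and mTEChi replicate 1 (59.8%) coincide. The p53 target markers all lie to the right of the dotted lines, and the Aire-dependent antigen markers all lie to the left.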

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

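The background without olfactory and vomeronasal receptor genes was the 1 setting chosen only after the data were seen. It left all p53 target results on the same side of the threshold. Over all settings, single lists, named genes and regions were the same in 1133 comparisons, moved in 183, gained a call in 9 and lost one in 30. List calls that a library of the other state cannot change were left out. In 6 of these comparisons the odds ratio was infinite because every member was called. The 1133 still hold comparisons fixed in advance. Named genes and regions have libraries that agree within each state, so leaving out 1 library cannot change their class. Nor can the 75 bp setting change the named regions, or the receptor background the named genes. The main results were the same in 69 comparisons, moved in 36, reversed in 3 and lost a call in 2. The 69 also hold comparisons fixed in advance. The replicate block cannot change a difference of means, and the cut at the median sets the difference in peak number. Receptor genes are not p53 targets, so leaving them out cannot change the number of state-specific targets. No permutation test over libraries could gain or lose a call. With only the peaks above each list's median score, 3506 mTEClo-only, 2711 mTEChi-only and 3028 shared regions were left, 0 lists passed in mTEClo, the mTEClo odds ratio of p53 targets was 2.35 and 2 targets were mTEChi-only. The 10000 highest peaks gave 1008, 1122 and 1369 regions, with the order of the states turned, 3 lists in mTEChi, 0 mTEClo-only and 3 mTEChi-only targets, and a gene end difference of -2.44 percentage points, the reverse of the full lists. Equal list lengths gave 1 list in mTEClo and 3 mTEChi-only targets. Summits within 75 bp gave 4584, 2961 and 2562 regions, fewer by construction. Windows of 1 kb gave 4 mTEChi-only targets; 25 kb gave 1 list in each state and 0 state-specific targets, and the gene body gave 0 mTEClo-only targets. Leaving out 1 library moved the difference in peak number from -10050 to 10400 (-10050 without mTEClo replicate 1 and -5724 without mTEChi replicate 1), the overlap ratio from 1.03 to 1.58 and the gene end difference from 0.528 to 2.13. It moved mTEClo-only regions from 8694 to 68954, mTEChi-only regions from 5696 to 68349, shared regions from 6000 to 7726, lists passing to 0 and 1 in mTEClo and to 5 in mTEChi (each without a library of its own state), and p53 odds ratios from 2.63 to 4.45 and 4.37 to 14.2. State-specific targets ran from 1 to 3 (mTEClo) and 1 to 8 (mTEChi). Where fewer peaks or libraries do not account for a change by construction, the cause was not tested. Replicate numbers are the same in both states, and deviations between replicates correlated at 0.0125 over 259773 regions. Of these regions 85.4% lie in 1 library, where 1 of the 2 deviations is 0, which holds the correlation near 0. It therefore cannot decide whether samples with the same replicate number share more than that number. With the replicate block the differences stayed 175 peaks (exact sign-flip p = 1) and 1.33 points (exact sign-flip p = 0.5, the smallest 2 pairs allow). Motif alternatives were not run without a genome sequence, restriction to chromosomes 1 to 19 and X changed nothing because all peaks lie there, and equal list lengths allow no difference in peak number. Unknown depth limits every count of missing peaks.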

Other observations

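The gene families and the tests of single-library regions, of chromosome X and of p53 targets against active genes were chosen only after the results were seen; the rank test at p53 targets was written down before its result. Large receptor families were almost free of repeated peaks. Of 1110 olfactory receptor genes, 50 (4.50%) were called in both mTEClo libraries and 36 (3.24%) in both mTEChi libraries (odds ratios 0.0404 and 0.0329), against 51.3% and 48.1% of all protein-coding genes, and 4 were called in all 4. Vomeronasal receptors had 7 of 353 in each state (0.0186 and 0.0212), and beta-defensins, antimicrobial peptide genes, 8 and 4 of 42 (0.222 and 0.113). Serpins had 20 and 19 of 63 (0.440 and 0.465; Fisher's exact test, adjusted p over 12 families 0.00442 and 0.00875).

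Genes of protein synthesis and respiration lay at the other end. Ribosomal protein genes were called for 56 (70%) and 64 (80%) of 80 members in both mTEClo and both mTEChi libraries (odds ratios 2.22 and 4.34; Fisher's exact test, adjusted p = 0.00246 and 2.54e-08). Mitochondrial ribosomal proteins had 58 of 78 in each state (2.76 and 3.14) and complex I subunits 30 and 29 of 40 (2.85 in each). Solute carriers had 21 members called in both mTEClo libraries alone, among them Slc12a1 and Slc30a10, and 4 in both mTEChi libraries alone. The exact sign test, which sets these counts against an equal split, gave p = 0.000911 (adjusted p = 0.0109 over 12 families). Other genes also had more mTEClo-only than mTEChi-only members, 743 against 478, and against that ratio Fisher's exact test gave p = 0.0211 (adjusted p = 0.254), which did not pass. The 2 genes were picked after their class was seen.

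Of all regions, 85.4% were called in 1 library alone. Fragments piled up without regard to genes are argued against as the whole cause. Single-library regions lay within 1 kb of a gene end at least 1.43 times as often as shifted peaks in each library (up to 2.27 times). Shifted peaks stand only for such placement, and no control library was analysed here. Background that itself lies more often at gene ends therefore cannot be told apart by this comparison. Sites shared by the libraries that pass the calling threshold in only some of them remain a candidate explanation: at least 99.4% of the 500 highest scores of each list were found in another library, against 18.4% to 22.6% of the lowest quartile. However, only 42.7% to 61.3% of the highest quartile were found in another library. With every tied peak given the best rank of its tie, single-library regions had a median rank at 45.5% to 55.5% of their list from the top. Many scores are tied, so these medians are placed too high and are not used as an argument. From the highest quartile alone, the candidate is not shown to cover peaks with scores well above the threshold. No biological explanation was tested for regions that differ between replicates of 1 state.

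Chromosome X held few peaks: 0.493% and 0.329% in mTEClo and 0.677% and 0.885% in mTEChi, against 4.47% of protein-coding genes. Removal of whole 10 Mb bins of the chromosome is argued against, because every full bin that holds genes held peaks, at least 40 over the 4 libraries; removal of smaller blocks was not tested. A single X copy per cell cannot be told apart from other causes, since the labels give no sex; peaks per gene were at most 0.191 of the autosomal number (0.0706 at the lowest), and lower coverage may lose more peaks than in proportion when a calling threshold is applied. The share was higher in both mTEChi libraries than in both mTEClo libraries (two-sided exact permutation test, p = 0.333, the smallest this design allows), and that difference between the states stays open.

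The excess of peaks at p53 targets may be general occupancy of the ends of active genes rather than binding of p53. Against 40 housekeeping and BAF subunit genes, of which both mTEChi libraries called 33, p53 targets (38 of 44) had an odds ratio of 1.34 (95% interval 0.346 to 5.35; Fisher's exact test, p = 0.765), and in mTEClo the counts were 31 of 40 and 33 of 44 (0.872, p = 0.804). These intervals are too wide to tell the 2 apart, and the antibody named in the protocol text, the lack of a control library analysed here and the motif search not run keep both open.

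A hypothesis written down beforehand held that p53 targets rank higher in mTEChi, from the percentile of each gene's best score among 7793 genes called in all 4 libraries. The median shift of 29 targets was 1.77 percentile points toward mTEChi, inside the 95% range of random lists matched on mean rank (-7.22 to 8.17), with 17 of 29 positive (permutation p = 0.731, adjusted p = 0.892 over the 10 lists with at least 5 members). Members went both ways, from Fas (60), Trp53inp1 (34.2), Bax (32.4) and Cdkn1a (32) to Btg2 (-35.4), Ckap2 (-39.5) and Polk (-45.0), all named after their values were seen. Another division of the libraries, replicate 1 against replicate 2, moved the same list more, with a median of -9.63, which lies 9.97 from its random median (permutation p = 0.00720, adjusted p = 0.0720). The test gave no support for a shift between the states; on simulated ranks of 7793 genes a planted shift of 15 points was found as 11.6 (permutation p = 0.00750).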
